A study of Homo sapiens with 6 samples.

How the data were processed

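Gene expression was measured in 6 libraries of cells labelled HL-60, 3 exposed to CIP and 3 to DMSO, with group and replicate number taken from the sample titles. The files hold whole-number read counts per gene symbol, 1 library per file, per the file headers. The counts were deposited by the authors without normalization, as far as the values show, since they are whole numbers with unequal totals. The submitters' processing notes name bcl2fastq 2.20.0.422, fastp, STAR and HTSeq and the genome build GRCh38, with no role, order or setting. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Libraries were made with a Lexogen QuantSeq kit from total RNA, per the labels' protocols. Such libraries count about 1 read per transcript end and not per length, so genes with similar 3' ends or with several poly(A) sites can be miscounted. Whether molecular identifiers were used is not given in the sources used here, so intervals and floors cover counting error only.

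The files list 43424 symbols, of which 22384 had at least 1 count, and hold no summary lines of unassigned reads. Positions come from the RefSeq table of GRCh38.p14, matched by symbol for 42739 symbols, which hold 99.7% of all counts. Within groups, pairs of libraries differed by more than sampling noise (chi-square per gene 4.02 to 8.33), so no library was treated as a duplicate. Of 201 named genes, 96 overlap another annotated gene, and because the strand setting is not given, reads of overlapping and antisense genes cannot be separated. Genes with near-identical copies (HLA genes, histones, TPSAB1, HSPA1A, RPL23A) are reported as uncertain.

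Genes were tested with edgeR 4.0.16 (quasi-likelihood test with robust dispersion, R 4.3.3) on the counts after filterByExpr and TMM scaling, group alone in the design, 2-sided, with Benjamini-Hochberg adjustment over the 12844 genes kept. A gene was called at an adjusted p under 0.05. The TMM factors were 0.914 to 0.930 in the CIP-labelled and 1.07 to 1.09 in the DMSO-labelled libraries. CPM values are counts divided by TMM-scaled library totals, in the usual CPM unit, given as mean ± SD over 3 libraries. The SE of a log2 fold change is its size divided by the square root of F. An exact permutation test of single values cannot go below p = 0.10 with 3 against 3 libraries, so p-values come from models over all genes. A library's 3 counts correspond to 0.287 to 0.346 CPM, and 3 counts over a group to 0.106 CPM (CIP) and 0.102 CPM (DMSO). For a gene with 0 counts in a group the fold is a lower bound against 3 counts over the group. With 1 to 3 counts, the ratio of summed counts is given with its exact 95% interval.

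Before the data were examined, 49 gene lists were fixed, covering myeloid maturation, markers of other cell types, stress and metabolic pathways, drug handling, RNA quality and genes lost or amplified in the line. Lists with at least 5 tested members (46 lists) were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, against all other tested genes. Camera with an estimated correlation and fry were run beside it. The pattern fixed for mitochondrially encoded genes found no symbol in the files, which name these genes without a prefix. It was read, after the files were seen, as the 13 protein-coding genes that RefSeq places on the mitochondrial chromosome. Some lists share genes, at most 5 between any pair.

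Named genes follow a rule. They are the 10 called genes per direction with the largest log2 fold change, a mean of at least 10 CPM in the higher group and libraries that separate (symbols that are only locus numbers left out). To these were added up to 4 called members of each list with the largest changes at 5 CPM or more, the 4 genes per direction with the largest difference in CPM, and 17 genes fixed whatever their values. Some genes that the rule takes are not reported here. In the text, a list's examples are a part of those the rule takes.

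Counts were simulated with the means of the DMSO-labelled libraries and the library sizes and dispersions of these data (12282 genes tested). The same steps recovered 34 of 67 genes changed 1.5-fold, 54 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 8 false calls. Changed genes were drawn only from those above a minimum expected count, so recovery near the floor was not measured. A simulated changed list was called and 0 of 40 unchanged lists were. Genes were simulated independently and few were changed. The simulation therefore cannot show how often the preset correlation gives false list calls in these data.

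Alternatives fixed in advance were RLE and upper-quartile scaling, library totals alone, no low-count filter, a filter of 1 CPM in 3 libraries, dispersion without robust fitting, DESeq2 1.42.0, limma-voom, thinning to the smallest library, leaving out mitochondrial genes, the replicate number as a block and each library left out in turn. A test beyond 2-fold, fold changes less the chromosome median and the calls shared by 3 tests were added after the data were seen. Chromosome medians given as such used genes with a mean of at least 10 CPM over all libraries. The medians taken out of fold changes used all tested genes of a chromosome, whatever their CPM. GC content was the mean over GENCODE v29 transcripts of a gene symbol. Figures were drawn with matplotlib 3.10.9. Genes of the sex chromosomes entered the tests and the medians taken out of fold changes, but not the autosome medians given.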

Results

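The series compared HL-60 cells, a human acute myeloid leukaemia line, after 6 months of culture with either DMSO or an extract of the plant Corydalis incisa (Thunb.) Pers., abbreviated CIP. The concentration of CIP was raised from 2 to 20 µg/ml over that time, and the series describes the surviving cells as resistant to CIP. Its stated aim was to find genes that take part in the differentiation of leukaemia cells that CIP brings about. Gene expression was measured with QuantSeq, a 3' method that reads a short stretch near the polyadenylated end of each transcript. There were 3 libraries labelled CIP and 3 labelled DMSO. Total counts were 9314584, 10553366 and 10868396 in the CIP-labelled libraries and 9287611, 9759687 and 8143657 in the DMSO-labelled ones, replicates 1 to 3 in turn. Between 15609 and 17524 genes had at least 1 count in a library. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

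The groups differed in most genes that could be tested. MPO, the myeloperoxidase of primary granules, stood at 8667 ± 282 CPM (TMM-scaled counts, SD, n = 3) in the CIP-labelled libraries and at 1.12 ± 0.32 CPM (n = 3) in the DMSO-labelled ones. PRG2, the major basic protein of eosinophil granules, stood at 6237 ± 192 against 1.41 ± 0.996 CPM. In the other direction CLEC2B, a C-type lectin, stood at 0.587 ± 0.501 CPM in the CIP-labelled libraries and at 1509 ± 193 CPM in the DMSO-labelled ones, and MEIS1, a homeobox transcription factor of progenitor cells, had 0 counts against 108.3 ± 6.7 CPM. By list, 69 of 83 cytosolic ribosomal protein, 21 of 28 ribosome biogenesis and 15 of 18 endoplasmic reticulum unfolded protein response genes were higher in the CIP-labelled libraries. In turn 20 of 27 lysosome and autophagy, 8 of 12 monocyte and macrophage and 15 of 23 TNF and NF-kB response genes were lower. Each of these lists was called with camera's preset correlation (adjusted p = 1.0e-13 to 0.018) and not with an estimated correlation (adjusted p = 0.30 to 0.35).

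Because all libraries carry the name of one line, genes known to mark HL-60 were read in each library first. HL-60 is known to carry extra copies of MYC, a transcription factor of growth genes, and to make abundant myeloperoxidase. MPO had 77887, 82824 and 84917 counts in the CIP-labelled libraries and 15, 9 and 9 counts in the DMSO-labelled ones. MYC (chromosome 8, 127735434 to 127742951, GRCh38) stood at 279.6 ± 52.2 CPM against 41.8 ± 3.9, a log2 fold change of 2.74 ± 0.13 (SE, edgeR adjusted p = 1.7e-10). CDKN2A, which encodes the p16 and p14ARF inhibitors of growth, fell from 111 ± 16.1 CPM in the DMSO-labelled libraries to 28.4 ± 2.37 CPM. It was listed in advance among the genes lost or amplified in the line. It had 222 to 294 counts in each CIP-labelled library and 1028 to 1149 in each DMSO-labelled one. Under both labels this goes against a loss of the whole gene, unless the reads come from overlapping genes such as CDKN2B-AS1. Of the 5 genes listed in advance as lost or amplified in the line, 1 rose, 3 fell and 1 did not pass, and the list was not called (camera adjusted p = 0.87). Lost and amplified genes would go in opposite directions, so that test of 1 direction cannot decide on the identity of the line. The MYC and MPO values of the DMSO-labelled libraries go against the background given for HL-60. The groups are therefore named by their labels throughout, and rose and fell mean higher and lower with the CIP label.

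**Figure D1:**
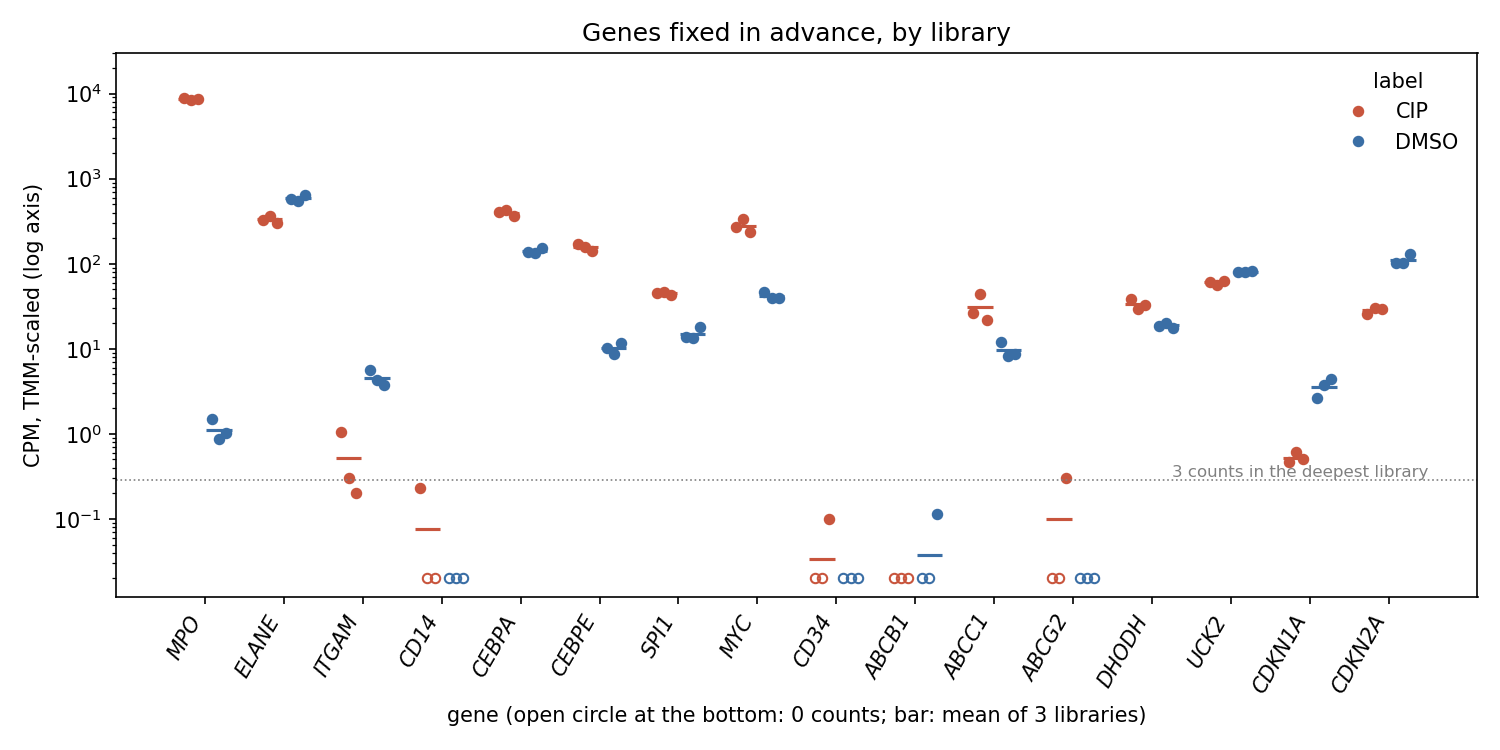
CPM on a log axis of 16 genes fixed in advance, 1 point per library, with a bar at the mean of each group of 3 and open circles for libraries with 0 counts. MPO lies near 8667 CPM in the CIP-labelled libraries and near 1.12 CPM in the DMSO-labelled ones.

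Of 12844 genes tested with edgeR's quasi-likelihood test, 9394 (73.1%) were called at an adjusted p under 0.05, 4482 of them higher and 4912 lower with the CIP label. At least a 2-fold change was found for 5014 of these, 1933 higher and 3081 lower, and a test of change beyond 2-fold, chosen after the data were seen, called 3689. Among all tested genes, all libraries of one group lay above all of the other for 9691 (75.5%), a separation that chance gives for 10% of genes with 3 against 3 libraries. The first principal component held 93.7% of the variance and separated the labels. Spearman correlations across tested genes, which are not independent replicates, were 0.989 to 0.992 within groups and 0.804 to 0.813 between them. With library totals in place of TMM scaling, 63.1% of the called genes were lower (3459 higher and 5913 lower) in place of 52.3%. The median log2 fold change of all tested genes then moved from -0.03 to -0.26.

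Many genes were abundant with one label and had no reads with the other. There were 50 genes at 10 CPM or more in the CIP-labelled libraries with 0 counts over the DMSO-labelled ones, and 64 genes the other way round. Folds for such genes are lower bounds against 3 counts over the group. ANKRD18A (chromosome 9, 38566151 to 38620596) reached 146.7 ± 9.12 CPM and was at least 1442-fold higher with the CIP label. SVIP (chromosome 11, 22818927 to 22829801), an inhibitor of protein degradation from the endoplasmic reticulum, reached 146.6 ± 7.88 CPM and was at least 1435-fold higher. IGF2BP1 (chromosome 17, 48996558 to 49056145), an RNA-binding protein of fetal tissues, reached 125.8 ± 8.87 CPM and was at least 1229-fold higher. DACH1, RHEX, PRAME, HPDL and the noncoding RNA MIR4458HG were at least 446-fold to 741-fold higher. PRAME is a tumour antigen, and RHEX regulates erythroid expansion. MPO itself (chromosome 17, 58269855 to 58280935) had a log2 fold change of 12.90 ± 0.12 (SE, edgeR adjusted p = 9.3e-41).

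MEIS1 (chromosome 2, 66435125 to 66573869) was at least 1027-fold lower with the CIP label. TPSAB1 (chromosome 16, 1240705 to 1242554), a mast cell tryptase, fell at least 1021-fold from 107.9 ± 6.47 CPM, with the limit that its reads can be shared with the near-identical TPSB2. IRF8 (chromosome 16, 85899162 to 85922609), a transcription factor of monocyte and dendritic lineages, was at least 448-fold lower, from 47.5 ± 3.18 CPM. The metallothionein MT1F, the receptor tyrosine kinase NTRK3, the homeobox gene UNCX, the phosphodiesterase PDE9A, the cholesterol hydroxylase CYP46A1, YPEL3-DT and HLA-DRB1 were at least 366-fold to 507-fold lower. HLA-DRB1 is uncertain, since its reads can be shared with other HLA genes and depend on the allele. By difference in CPM, RPS29, MPO and the mitochondrial transcripts ND3 and COX2 rose most. RPS29 went from 6015 ± 593 to 17974 ± 1361 CPM. ATP6, CLEC2B, the chaperone HSP90AB1 and the condensin subunit SMC4 fell most by that measure, and SMC4 went from 1762 ± 57.9 to 476.4 ± 22.6 CPM.

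Myeloid genes moved in both directions. Of 14 tested primary granule genes 5 rose, 8 fell and 1 did not pass. MPO rose, while RNASE3, an eosinophil ribonuclease, fell from 342.7 ± 4.6 to 13.6 ± 0.482 CPM, lysozyme (LYZ) fell from 231.9 ± 9.82 to 17.7 ± 4.11 CPM and SERPINB1, an inhibitor of neutrophil proteases, fell from 483.8 ± 9.78 to 34.2 ± 7.38 CPM. ELANE, neutrophil elastase, had a log2 fold change of -0.83 ± 0.07 (SE). The list was called lower (camera adjusted p = 0.018, adjusted p = 0.30 with an estimated correlation). All 5 tested secondary and tertiary granule genes fell, among them FCN1, from 26.2 ± 1.76 CPM to 2 counts over the group (370 times lower, exact 95% interval 102.2 to 3064), and the metalloproteinases MMP25 and MMP9. That list was called lower (camera adjusted p = 0.034, adjusted p = 0.35 with an estimated correlation), and not with library totals alone (adjusted p = 0.056). CHI3L1, the remaining one of them above 5 CPM, fell with an adjusted p of 0.043, which was 0.072 when libraries were thinned to the total count of the smallest, 0.16 without CIP replicate 1 and 0.10 without DMSO replicate 2. Of 15 mature neutrophil genes 2 rose, 9 fell and 4 did not pass (camera adjusted p = 0.068). The integrin subunit ITGB2 fell from 1276 ± 68.9 to 183.8 ± 20.8 CPM, and ITGAM (CD11b), a marker of myeloid maturation, fell from 4.56 ± 0.979 to 0.516 ± 0.456 CPM. The primary granule list did not pass with the replicate block (adjusted p = 0.17), nor without CIP replicate 3 (0.13) or DMSO replicate 3 (0.0514). With no filter on low counts it did not pass either (adjusted p = 0.11), and its median log2 fold change turned from -0.82 to 0.19. The mature neutrophil list passed with no filter on low counts (adjusted p = 0.022) and without CIP replicate 1 (0.049).

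Monocyte and macrophage genes fell in 8 of 12 cases, with 1 rising and 3 not past the test (camera adjusted p = 0.0046, adjusted p = 0.30 with an estimated correlation). The median log2 fold change of -2.10 was -0.33 with no filter on low counts, -1.39 without CIP replicate 1 and -0.98 without CIP replicate 2, with the call kept. The lysosomal protease CTSB fell from 211.5 ± 9.68 to 19.0 ± 3.18 CPM, CD68 from 17.0 ± 1.75 to 0.690 ± 0.301 CPM and LGALS3 from 15.1 ± 1.61 to 0.304 ± 0.302 CPM. CD14 was not tested, with 2 counts over the CIP-labelled libraries and 0 over the others. Of 6 eosinophil, basophil and mast cell genes 4 rose and 2 fell (camera adjusted p = 8.1e-05, adjusted p = 0.30 with an estimated correlation). With genes at 0 set to their bound, the median log2 fold change of that list was 5.67 in place of 7.15. PRG2, the eosinophil peroxidase gene EPX and CLC rose, the latter pair from 0 counts to 5.98 ± 2.04 and 11.4 ± 2.9 CPM, and TPSAB1 fell. The eosinophil ribonuclease RNASE3, which was counted with the primary granule genes and not in that list, also fell. The call was lost with the replicate block (adjusted p = 0.092) and without CIP replicate 3 (0.0505). Of 5 lymphoid genes 4 fell and 1 did not pass (camera adjusted p = 0.034, adjusted p = 0.30 with an estimated correlation). They included NKG7, a granule protein of cytotoxic cells, from 79.5 ± 12.2 to 3.19 ± 0.442 CPM, and the B-cell transcription factor PAX5, from 7.99 ± 0.873 to 0.251 ± 0.132 CPM. That call was lost with library totals alone (adjusted p = 0.055), with no filter on low counts (0.22, median log2 fold change -0.87 in place of -4.64) and without CIP replicate 3 (0.0505).

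Among other lineages, 1 of 4 erythroid genes rose, the transferrin receptor TFRC, from 45.5 ± 1.41 to 532 ± 21.3 CPM, and 2 fell, GYPC and EPOR. Both tested megakaryocyte genes rose, NFE2 among them from 18.3 ± 3.48 to 87.7 ± 5.56 CPM. Of the 2 tested dendritic cell genes TCF4 rose and BATF3 fell. These 3 lists had too few members to test as lists. Of 10 epithelial, fibroblast and endothelial genes 2 fell, PECAM1 and VIM, and 8 did not pass (camera adjusted p = 0.28). VIM stood at 77.6 ± 8.47 against 179 ± 14.4 CPM. The 8 that did not pass, which include collagen and keratin genes, had reads with both labels. FN1 stood at 59.4 ± 33.1 against 120.6 ± 29.2 CPM and COL1A1 at 12.1 ± 3.14 against 19.6 ± 12 CPM. The source of these reads was not tested.

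Transcription factors and progenitor genes also split. Of 20 myeloid transcription factor genes 10 rose and 8 fell (camera adjusted p = 0.063). CEBPE, needed for late granulocyte maturation, rose from 10.2 ± 1.56 to 157 ± 16 CPM, a log2 fold change of 3.95 ± 0.11 (SE, edgeR adjusted p = 5.1e-26). CEBPD rose from 3 counts over the DMSO-labelled libraries to 47.3 ± 7.2 CPM, 462 times higher (exact 95% interval 158 to 2241). CEBPA rose from 139.6 ± 10.1 to 395.3 ± 30.9 CPM, and SPI1 (PU.1) rose from 15.0 ± 2.49 to 45.1 ± 1.55 CPM. Of 11 stem and progenitor genes 5 rose and 6 fell (camera adjusted p = 0.73). KIT, the stem cell factor receptor, rose from 0.468 ± 0.367 to 42.2 ± 0.91 CPM, while HOXA10 fell from 224.9 ± 5.52 to 4.25 ± 0.419 CPM and CD38 fell from 5.30 ± 1.24 CPM to 0 counts. CD34 was at 1 count over all libraries. Chromatin regulators of myeloid differentiation rose in 12 and fell in 4 of 23 cases (camera adjusted p = 0.068, with 0.0091 when low counts were not filtered, and 0.037 to 0.040 without CIP replicate 1, CIP replicate 2 or DMSO replicate 2), and TET2, a methylcytosine dioxygenase, rose from 7.14 ± 1.05 to 45.7 ± 2.46 CPM. Of 9 retinoid response genes 4 rose and 4 fell (camera adjusted p = 0.46).

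Of 83 cytosolic ribosomal protein genes 69 rose, 10 fell and 4 did not pass (median log2 fold change 0.77, camera adjusted p = 1.0e-13, adjusted p = 0.30 with an estimated correlation). Together these genes took 23.3% to 23.9% of the counts of a CIP-labelled library and 16.2% to 17.3% of a DMSO-labelled one. RPS25 rose from 339.9 ± 13.8 to 1029 ± 157 CPM, while RPL39L, a paralog of RPL39, fell. RPL23A, at 3442 ± 656 against 1113 ± 67.9 CPM, is uncertain because many processed pseudogenes resemble it. Of 28 ribosome biogenesis genes and MYC targets 21 rose, 0 fell and 7 did not pass (camera adjusted p = 6.9e-04, adjusted p = 0.35 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, rose from 123.02 ± 2.87 to 299.8 ± 11.9 CPM and the lactate dehydrogenase gene LDHA from 191.7 ± 18.3 to 466.7 ± 45.1 CPM. Of 18 genes of the endoplasmic reticulum unfolded protein response 15 rose, 1 fell and 2 did not pass (median log2 fold change 0.90, camera adjusted p = 3.0e-04, adjusted p = 0.30 with an estimated correlation). The chaperone calreticulin (CALR) rose from 901.2 ± 54 to 2733 ± 125 CPM, and SDF2L1, CRELD2 and DNAJB9 rose as well. Proteasome genes rose in 17 and fell in 2 of 30 cases (camera adjusted p = 0.045, adjusted p = 0.30 with an estimated correlation), a call lost with RLE scaling (adjusted p = 0.0525) and with library totals alone (0.16), where the median log2 fold change was 0.08 in place of 0.31.

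**Figure D2:**
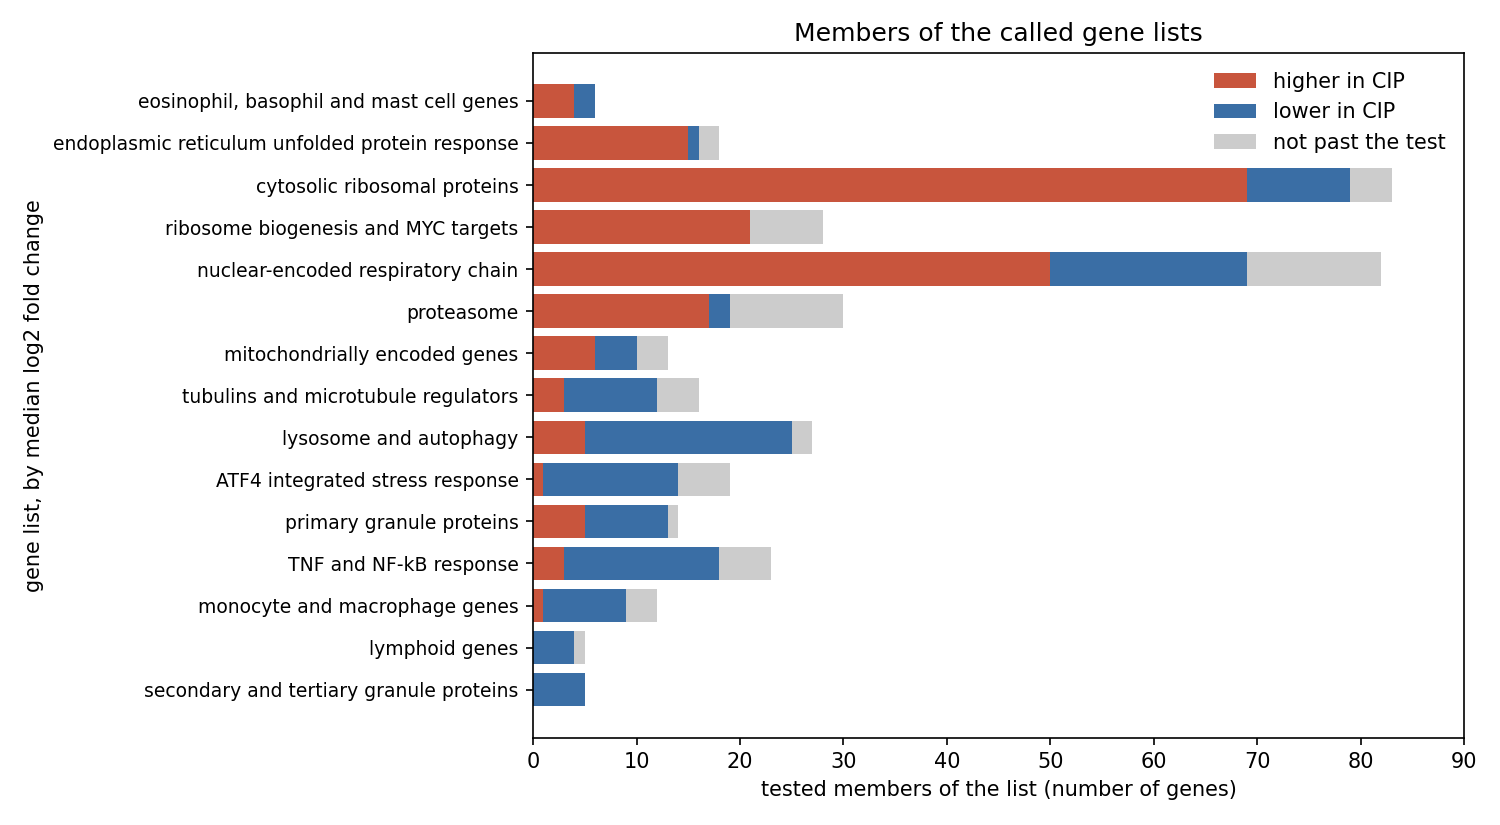
Number of tested members of each of the 15 called gene lists that were higher, lower or not past the test in the CIP-labelled against the DMSO-labelled libraries, lists ordered by median log2 fold change. In the cytosolic ribosomal protein list 69 of 83 genes were higher, and in the lysosome and autophagy list 20 of 27 were lower.

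Of 27 lysosome and autophagy genes 20 fell, 5 rose and 2 did not pass (median log2 fold change -0.65, camera adjusted p = 4.1e-04, adjusted p = 0.30 with an estimated correlation). WIPI1, a protein of autophagosome formation, fell from 6.84 ± 0.792 to 0.522 ± 0.257 CPM, and TFEB, the transcription factor of lysosome biogenesis, fell from 12.5 ± 0.867 to 0.443 ± 0.416 CPM. Of 23 TNF and NF-kB response genes 15 fell and 3 rose (camera adjusted p = 0.018, adjusted p = 0.30 with an estimated correlation). The chemokine CCL5 fell from 207.1 ± 12.7 to 4.05 ± 1.63 CPM, and BCL2A1, an inhibitor of apoptosis, fell from 68.3 ± 6.83 to 0.969 ± 0.369 CPM. Of 19 ATF4 integrated stress response genes 13 fell and 1 rose (camera adjusted p = 0.034, adjusted p = 0.30 with an estimated correlation). SESN2 fell from 63.1 ± 5.43 to 9.99 ± 0.726 CPM and PHGDH, the first enzyme of serine synthesis, from 246.7 ± 10.8 to 92.9 ± 7.62 CPM. Serine and one-carbon metabolism genes fell in 9 and rose in 2 of 13 cases (camera adjusted p = 0.063). That list passed without any one of the 6 libraries (adjusted p = 0.035 to 0.047), with the replicate block (0.045), with library totals alone (0.031) and with no filter on low counts (0.016).

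Of 16 tubulins and microtubule regulators 9 fell, 3 rose and 4 did not pass (camera adjusted p = 0.0052, adjusted p = 0.35 with an estimated correlation). TUBB6 fell from 79.8 ± 5.99 to 0.313 ± 0.086 CPM and TUBA4A from 222.2 ± 3.56 to 10.9 ± 0.859 CPM. TUBB3, a marker of taxane resistance, fell from 10.9 ± 2.14 CPM to 3 counts over the group, 102 times lower (exact 95% interval 34.6 to 497). Replication-dependent histones, whose transcripts mostly lack a poly(A) tail, rose in 3 and fell in 6 of 18 cases (camera adjusted p = 0.95) and share near-identical copies.

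No MHC or interferon response list was called. Of 6 MHC class II genes 5 fell and 1 rose (camera adjusted p = 0.068), with a median log2 fold change of -7.55, or -4.52 with genes at 0 set to their bound. The 1 that rose was CTSS, a protease and not an MHC molecule. HLA-DRA, HLA-DRB1, HLA-DRB5 and the regulator CIITA had 0 counts over the CIP-labelled libraries. CD74 fell from 6.60 ± 1.56 to 1.11 ± 0.362 CPM. HLA-DRA reached only 1.47 ± 0.121 CPM with the DMSO label, and HLA reads are uncertain. Of 16 MHC class I genes 6 rose and 5 fell (camera adjusted p = 0.56). PSMB10, of the class I list, rose from 30.2 ± 4.39 to 104.1 ± 4.06 CPM. HLA-C fell from 417.6 ± 11.7 to 128.7 ± 13.8 CPM, a value that can depend on the allele and on reads shared with other HLA genes. Of 32 interferon response genes 4 rose and 14 fell (camera adjusted p = 0.24). The antiviral GTPase MX2 fell from 111.4 ± 12.4 to 1.36 ± 1.12 CPM.

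Among genes that handle drugs, ABCB1 (P-glycoprotein) was at 1 count and ABCG2 at 3 counts over all 6 libraries, and neither was tested. ABCC1, an efflux transporter, rose from 9.73 ± 2.11 to 30.6 ± 12 CPM (log2 fold change 1.65 ± 0.25, SE, edgeR adjusted p = 4.0e-05), and ABCA2 rose from 2.27 ± 0.207 to 22.7 ± 0.83 CPM. ABCA3 fell from 15.9 ± 1.59 CPM to 0 counts, at least 149.5-fold. Of the 9 tested genes listed as ABC drug transporters 3 rose and 4 fell (camera adjusted p = 0.99). LRP1, an endocytic receptor, and MVP, the major vault protein, are among the 4 and are not ABC transporters. Of 18 NRF2 targets 3 rose and 10 fell (camera adjusted p = 0.24), NQO1, a quinone reductase, from 34.9 ± 7.93 to 4.99 ± 0.783 CPM. Of 15 AHR targets and xenobiotic enzymes 6 rose and 7 fell (camera adjusted p = 0.99), and the cytochrome P450 gene CYP1B1 rose from 1.31 ± 0.614 to 32.002 ± 3.32 CPM.

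Nucleotide genes moved in both directions. Of 15 genes of de novo pyrimidine and deoxythymidylate synthesis 9 rose and 4 fell (camera adjusted p = 0.24). DHODH, the mitochondrial enzyme of that pathway, rose from 18.8 ± 1.09 to 33.8 ± 4.49 CPM (log2 fold change 0.84 ± 0.14, SE, edgeR adjusted p = 1.5e-06), and UMPS rose from 41.6 ± 3.99 to 78.2 ± 3.52 CPM. Of 18 pyrimidine salvage and breakdown genes 8 rose and 8 fell (camera adjusted p = 0.99). Cytidine deaminase (CDA) fell from 67.7 ± 2.06 to 0.279 ± 0.205 CPM, the nucleoside transporter SLC29A2 rose from 1.42 ± 0.482 to 61.8 ± 3.67 CPM, and UCK2, a uridine-cytidine kinase, had a log2 fold change of -0.41 ± 0.09 (SE). Purine synthesis genes rose in 8 and fell in 2 of 14 cases (camera adjusted p = 0.068), and passed with no filter on low counts (adjusted p = 0.0091) and without CIP replicate 1, CIP replicate 2 or DMSO replicate 2 (0.037 to 0.040).

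Cell cycle and death genes showed no list-wide call. Of 29 G1/S and DNA replication genes 9 rose and 12 fell (camera adjusted p = 0.87), and of 29 G2/M and mitosis genes 3 rose and 16 fell (camera adjusted p = 0.096). The G2/M list passed with library totals alone (adjusted p = 0.042), with no filter on low counts (0.014) and without CIP replicate 2, DMSO replicate 2 or DMSO replicate 3 (0.037 to 0.046). The kinesin KIF20A fell from 34.9 ± 3.62 to 9.97 ± 0.838 CPM, while UBE2C rose from 36.4 ± 1.99 to 115.3 ± 10.1 CPM. Among CDK inhibitors and G1 cyclins 4 of 16 rose and 8 fell (camera adjusted p = 0.99). Cyclin D1 (CCND1) rose from 1.48 ± 0.434 to 43.7 ± 3.53 CPM, and the inhibitor CDKN1A (p21) fell from 3.60 ± 0.874 to 0.526 ± 0.0783 CPM. Of 18 p53 targets 6 rose and 6 fell (camera adjusted p = 0.95). BBC3 (PUMA) fell from 106.6 ± 7.68 to 12.6 ± 1.25 CPM, and ZMAT3 rose from 2.55 ± 0.335 to 30.7 ± 3.74 CPM. Of 28 apoptosis regulators 14 rose and 4 fell (camera adjusted p = 0.62), and BCL2, which blocks apoptosis, rose from 11.9 ± 0.369 to 59.3 ± 1.16 CPM. Receptor tyrosine kinase and RAS-MAPK feedback genes rose in 7 and fell in 6 of 14 cases (camera adjusted p = 0.15), and the feedback inhibitors SPRED1 and SPRY1 rose. Heat shock genes rose in 9 and fell in 5 of 17 cases (camera adjusted p = 0.81). The small heat shock protein HSPB1 fell from 484.6 ± 48.7 to 15.9 ± 1.95 CPM, and HSPA8 rose from 48.5 ± 9.2 to 334.1 ± 13.5 CPM.

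In energy metabolism, nuclear-encoded respiratory chain genes rose in 50 and fell in 19 of 82 cases (median log2 fold change 0.41, camera adjusted p = 0.017, adjusted p = 0.45 with an estimated correlation), a call lost with library totals alone (median 0.19, adjusted p = 0.11). Mitochondrially encoded genes rose in 6 and fell in 4 of 13 cases (median log2 fold change 0.15, camera adjusted p = 0.041, adjusted p = 0.35 with an estimated correlation), and with library totals alone the median turned to -0.07 and the call was lost (adjusted p = 0.12). That call was also lost with the replicate block (adjusted p = 0.12) and without any of CIP replicates 2 and 3 or DMSO replicates 1, 2 and 3 (0.0514 to 0.073). CYTB rose from 1796 ± 108 to 6976 ± 490 CPM while ATP6, on the same circular genome, had a log2 fold change of -0.24 ± 0.06 (SE). Mitochondrial transcripts took 11.6% to 13.2% of the counts of a library. Of 23 glycolysis genes 10 rose and 8 fell (camera adjusted p = 0.79). Hexokinase 1 (HK1) fell from 67.2 ± 2.9 to 1.48 ± 0.789 CPM. PGAM1, with libraries of the groups overlapping, rose from 1.90 ± 1.19 to 6.42 ± 5.31 CPM with an adjusted p of 0.037, which was 0.12 without CIP replicate 2, 0.13 without DMSO replicate 1, 0.091 without DMSO replicate 2 and 0.060 to 0.073 with limma-voom, DESeq2, library totals or the replicate block. Of 17 hypoxia genes 9 rose and 7 fell (camera adjusted p = 0.99), and PDK1 fell from 844.6 ± 19.3 to 75.6 ± 9.95 CPM.

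Lipid and iron genes went both ways. Of 23 genes of cholesterol synthesis and uptake 11 rose and 8 fell (camera adjusted p = 0.43), HMGCS1 rising from 100.7 ± 6.55 to 382.4 ± 23.9 CPM. Fatty acid synthesis and desaturation genes rose in 4 and fell in 8 of 14 cases (camera adjusted p = 0.64), and fatty acid oxidation genes rose in 5 and fell in 10 of 17 cases (camera adjusted p = 0.56). The thiolase ACAA2 fell from 29.5 ± 2.32 to 0.154 ± 0.267 CPM. Haem and iron metabolism genes rose in 5 and fell in 9 of 18 cases (camera adjusted p = 0.99), and the biliverdin reductase BLVRB fell from 103.5 ± 1.27 to 8.51 ± 3.74 CPM.

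Of 46 lists tested, 15 were called with camera's preset correlation, 7 higher and 8 lower, and 0 with an estimated correlation. By fry, which asks only whether the genes of a list change on balance in one direction, 42 of 46 passed. Adjusted over the list alone, the counts of rising and falling members were the same in 44 of 49 lists and differed by 1 gene in the other 5. Those were primary granule proteins (6 rose), the unfolded protein response (16 rose), histones (5 fell), mitochondrially encoded genes (7 rose) and the respiratory chain (20 fell). The median, the mean and the camera direction differed in sign in 10 lists, and 0 of these were called. They were the lists of myeloid transcription factors, MHC class I, ABC transporters, AHR targets, heat shock, p53 targets, CDK inhibitors, glycolysis, haem and iron, and retinoid response.

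Fold changes also followed chromosomes, a property examined after the values were seen. Among 7826 autosomal genes with a mean of at least 10 CPM over all libraries, those on chromosome 8 had a median log2 fold change of -0.99, with 228 of 262 falling. Those on chromosome 15 had a median of -0.64, with 194 of 297 falling. Genes on chromosome 18 had a median of 1.12, with 107 of 125 rising. MYC, on chromosome 8, rose while most of its chromosome fell, and BCL2, PMAIP1 and TCF4 rose with most genes of chromosome 18, on which ACAA2 and TUBB6 fell. Of the 22 autosomes, 11 had a median outside the range of 1000 random assignments of genes to autosomes. The median over all tested genes of each gene's own chromosome was also taken out. The median log2 fold change of the unfolded protein response list was then 0.69 in place of 0.90. That of the ribosomal protein list was 0.70 in place of 0.77 and that of the lysosome and autophagy list -0.44 in place of -0.65. For mitochondrially encoded genes, which help to set the median of their own chromosome, it was 0.01 in place of 0.15. Among lists that were not called, the median turned for MHC class I (from -0.04 to 0.18) and for G1/S and DNA replication (from -0.03 to 0.01), and that of receptor tyrosine kinase and RAS-MAPK feedback went from 0.26 to 0.08.

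**Figure D3:**
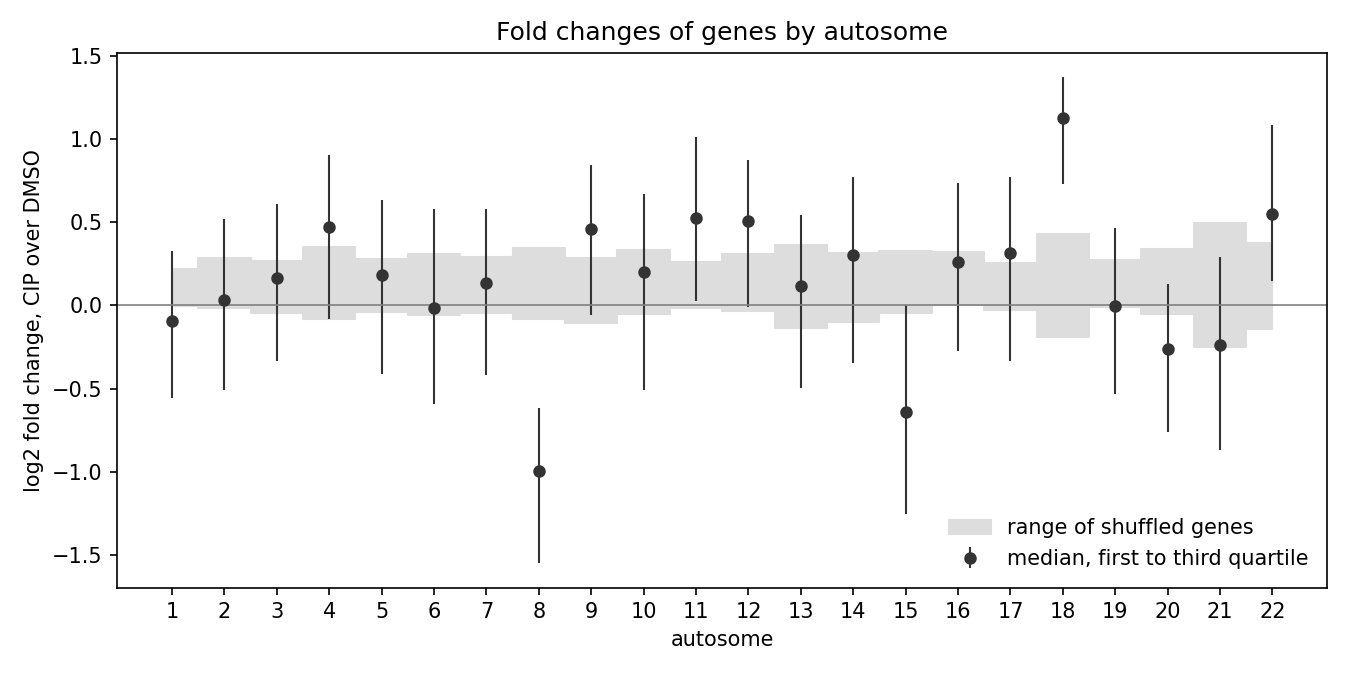
Log2 fold change, CIP-labelled over DMSO-labelled, of genes on each of the 22 autosomes, with points at the median, lines from the first to the third quartile and grey bands for the range of medians over 1000 random assignments of genes to autosomes. Chromosome 8 has a median of -0.99 and chromosome 18 a median of 1.12, both outside the band.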

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

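The test of a change beyond 2-fold, the fold changes less the chromosome median and the calls shared by 3 tests were chosen only after the results were seen. The count of called genes (9394) ran from 9061 to 10349 over the other settings and from 9152 to 9552 without any one library, and 0 genes called in both a setting and the reported test changed direction. With no filter on low counts 22384 genes were tested in place of 12844. Genes called with at least a 2-fold change (5014) ran from 4873 to 6109 over the settings fixed before. They numbered 3689 by the test of a change beyond 2-fold. With the chromosome median taken out of the fold change, and the adjusted p left as it was, they numbered 4545. Called alike by edgeR, DESeq2 and limma-voom were 9076 genes. Of 197 named genes tested, 195 kept their direction and their side of the threshold in each alternative run. The exceptions were CHI3L1 and PGAM1, whose calls ended in some settings without a change of direction. Calls of gene lists (15) numbered 14 with RLE scaling, 12 with library totals alone (10 of them shared), 18 with no filter on low counts (13 shared), 14 without mitochondrial genes and 12 to 19 without any one library. With an estimated correlation between genes 0 lists were called, the smallest adjusted p being 0.30. The estimate lay below the preset 0.01 for the monocyte (-0.020), lymphoid (-0.143) and ATF4 (-0.038) lists, and above it for the other called lists. Camera's unadjusted p still rose for those below, from 6.0e-04 to 0.022, 0.0093 to 0.057 and 0.0096 to 0.048. For these lists the rise in p thus did not come from a higher correlation. The cause of these shifts was not tested.

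The replicate numbers did not pair the samples, since the deviations of same-numbered libraries from their group means had correlations across genes of -0.023, -0.060 and -0.039, against a minimum of 0.10 set for pairing. No library of either group had its highest correlation with its own number. With the replicate block, 9061 genes were called, 9044 of them among the 9394, 4938 with at least a 2-fold change, and 13 lists, 12 of them shared. Depth limits the genes near 3 counts. Simulated 1.5-fold changes were recovered in 50.7% of cases, but were placed only in genes with more counts, so that share does not cover genes near 3 counts.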

Other observations

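The gene families and the genes named in the next paragraph and the tests of mixed cells, of different origin and of a few strongly changed genes were chosen only after the results were seen.

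Members of 7 gene families were counted by their calls. Tests of these families as sets were run but are void and not given, since the families were picked from these values. Some members, such as HOXA10, S100A8 and S100A9, are also in the fixed lists. All 5 tested metallothioneins, which bind zinc and copper, fell with the CIP label, MT1G from 262.7 ± 17.1 to 1.85 ± 0.327 CPM (n = 3 per group). Of 11 S100 calcium-binding proteins 10 fell, S100A6 from 520.1 ± 16.3 to 18.7 ± 4.54 CPM. All 7 tested genes with a SIGLEC symbol, of a family of receptors for sialic acid, fell, SIGLEC6 from 98.1 ± 15.4 to 5.03 ± 1.66 CPM. Receptors of that family under other symbols were not counted among them, and of these CD33 rose, from 65.6 ± 7.61 to 90.7 ± 5.26 CPM. Of 8 HOXA genes 5 fell and 2 rose. HOXA13 fell from 118 ± 10.02 to 10.1 ± 2.34 CPM and HOXA7 rose from 4.32 ± 1.46 to 13.5 ± 0.565 CPM. Of 18 interleukin receptors 13 fell and 2 rose. Zinc finger genes named ZNF rose in 212 and fell in 55 of 394 cases, with a median log2 fold change of 0.57, or 0.35 with library totals alone. Mitochondrial ribosomal protein genes rose in 48 and fell in 12 of 76 cases, with a median of 0.43, or 0.20 with library totals alone. Each family's median kept its sign with RLE, upper-quartile and library-total scaling. Among single genes, of which GATA2 and FLT3 are also in fixed lists, GATA2, a transcription factor of stem and mast cells, rose from 2.04 ± 0.833 to 88.7 ± 3.02 CPM, and the receptor FLT3 rose from 0.762 ± 0.384 to 25.5 ± 1.87 CPM. ANXA2, a phospholipid-binding protein, fell from 280.8 ± 16.1 to 1.22 ± 0.79 CPM and LGALS1, a galectin, from 590 ± 27.3 to 9.28 ± 1.37 CPM.

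With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labels gave 9394 called genes and 5014 with a 2-fold change, against at most 0 in the other splits by edgeR, where 8 to 28 genes had an unadjusted p under 0.05. The labels gave 15 called lists against at most 6. In each of these comparisons 1 of the 10 splits, the labelled one, gave a result as large. Each other split mixed the labels, so the difference between labels widened the spread within its groups. Their counts of called genes were bound to be low and do not measure what chance gives.

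Genes abundant with one label were nearly absent with the other. Of 1657 genes at 100 CPM or more in the CIP-labelled libraries, 11 lay under 1% of that level in the DMSO-labelled ones, and of 1606 genes the other way round, 25 did, which argues against either group holding 1% or more of the other's cells. Cell populations of different origin may underlie the labels, a hypothesis under which whole autosomes would differ. Medians of 11 of 22 autosomes lay outside the range of random assignments. That expectation was written after the values were seen, and the random assignments treat neighbouring genes as independent, so the count is no separate support. It also does not separate a different line or a mislabelled culture from a subclone selected during 6 months with CIP, which was not tested. MPO and MYC departed from the HL-60 background in the DMSO-labelled libraries (15, 9 and 9 MPO counts, MYC at 41.8 ± 3.9 CPM). If the labels are right, selection with CIP did not act there. For these genes the values thus argue against that selection as the whole source, while the source of the autosome shifts stays open.

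The median of chromosome 18 lay 2.12 above that of chromosome 8 on the log2 scale (bootstrap SE 0.0803). On chromosome 8, 87.0% of genes were called lower and on chromosome 18, 85.6% were called higher. The shares on the other autosomes were 31.7% and 44.3%. The shift was thus spread over most genes of both chromosomes. Both were picked by their medians, so these shares largely restate the medians and are no separate test of a few strongly changed genes. After the trend on transcript GC content was taken out, the difference of medians was 2.12 (SE 0.0794, and 2.13 before in the same genes), which argues against GC content as the whole source, while that correction moved single genes by a median of 0.12. The difference without genes changed over 4-fold was 1.97, by a test set before its own result but on chromosomes picked from these values. It decides nothing, since few genes hardly move a median. Medians over bins of chromosome 8, taken after its median was seen, decide nothing either, since the bins restate it. Copy number was not measured in these libraries, and the biological explanation that the exposure to CIP set these shifts was not tested.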
